A study of Gallus gallus with 9 samples.

How the data were processed

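RNA profiles of 3 chick embryonic tissues were analysed, periocular neural crest at E3, corneal endothelium at E5 and corneal endothelium with keratocytes at E7, in 3 libraries each, 9 in all. Per the labels' protocols, tissue was isolated and frozen in Trizol and RNA quality was examined on a Bioanalyzer. Samples were grouped by their titles, and no sample was left without a group.

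Per the file headers, the deposited files give an expected count, an estimate that need not be whole, and an FPKM value for each entry of each library. The authors computed both. Per the submitters' processing notes, Bowtie2, HISAT and the genome build galGal5 were used; their versions, the counting program, the annotation and the use of strand are not given in the sources used here. Each file lists entries above 0, the lowest listed FPKM being 0.01, so an entry missing from a library was taken as 0. The files held 46855 different entries, named by gene numbers or transcript accessions. Names came from a RefSeq gene table of assembly GRCg7b, another build than the authors', so no coordinates are given. By those names, 14120 genes had an entry, 5032 of them with 2 or more and at most 17, which were summed per gene. Between 76.5% and 78.6% of the counts of a library fell on these genes. The 22897 accession entries without a match, with 21.4 to 23.5% of the counts, stayed out of the gene tests. Their counts are part of the library totals, which set the library sizes and CPM.

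Library totals ran from 9874339 to 23205388 expected counts. A floor of 3 counts corresponds to 0.129 to 0.304 CPM per library. Folds against a group with 0 counts were computed against 3 counts over the group and are given as "at least"; with 1 to 3 counts, the ratio is given with its exact 95% binomial interval. These intervals and floors cover counting error only. Genes with near-identical copies, such as globins, may share reads.

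Expected counts were summed per gene, rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group and the quasi-likelihood F-test, on all 9 libraries in a fit without covariates. This left 11748 genes. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. Levels are the authors' FPKM, summed over the entries of a gene, as mean ± SD. Replicates were compared by a chi-square test of their counts. The procedure was tested on simulated data with 200 changed genes among 11748, drawn only from the better expressed genes. At 2-fold, 33, 44 and 41 of 100 genes were recovered for E5 against E3, E7 against E5 and E7 against E3, at 4-fold 79, 73 and 68, and 5, 4 and 8 unchanged genes were called.

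Groups, tests, gene lists, the naming rule and the alternatives were fixed before the data were examined, except where stated. There were 31 lists, 17 of biology, 11 of other cell types and 3 of quality, with 698 of 845 members having an entry. The biology lists were neural crest specification and migration, periocular mesenchyme transcription factors, stromal proteoglycans and keratan sulfate synthesis, collagens, collagen processing and crosslinking, endothelial pump, transport and junction, basement membrane, hyaluronan and matrix remodelling, retinoic acid, TGF-beta and BMP, WNT, FGF, axon and cell guidance, cell cycle and DNA replication, glycolysis and hypoxia, contractile and smooth muscle, and HOX genes. The lists of other cell types were erythroid cells, leukocytes, vascular endothelium, corneal epithelium and surface ectoderm, lens, neural retina, pigmented epithelium and melanocytes, skeletal myogenic cells, neurons, Schwann cells and glia, and cartilage. The quality lists were ribosomal proteins, immediate early and heat shock genes, and mitochondrial genes. The 29 lists with at least 3 measured genes were tested with camera (limma 3.58.1), with a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. No list was chosen on these samples.

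Genes were named by 4 parts of a rule. Per comparison, these were the 6 largest rises and falls among called genes with a mean FPKM of 10 or more in the higher group and libraries that did not overlap. Per list, up to 3 called members per direction with the largest change and a mean FPKM of 5 or more could be named. The 26 landmark genes, 24 of which had an entry, were named whether called or not, as was any called member of a list with 5 or fewer, except for a few genes that are not reported here. Overlap was first read on FPKM and then, after values had been seen, on CPM with TMM factors. All 24 choices of the first part, which count a gene once per comparison, were the same on both scales. Not every gene that the list part allows is printed.

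Alternatives were RLE factors, library size alone, DESeq2 1.42.0, no filter on counts, a mean FPKM of 1 or more, limma on log2(FPKM + 1) with and without that filter and with a pseudocount of 0.1, only the 6 libraries of the groups compared, the replicate number as a term, a log2 fold change of 1 or more, glmTreat, and each library left out in turn. Fold changes from limma are on the log2(FPKM + pseudocount) scale, which understates changes of low genes. Leaving out the third libraries of E5 and E7 together, and testing entries without summing them, were added after the data had been seen. Each comparison was also run for all 10 splits of its 6 libraries, and E7 against E5 again after thinning to the depth of the shallowest library.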

Results

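RNA was sequenced from 3 tissues of the chick embryo (Gallus gallus), each as 3 libraries: periocular neural crest at embryonic day 3 (E3), corneal endothelium at E5, and corneal endothelium taken with keratocytes at E7. Periocular neural crest cells migrate around the optic cup and build most of the cornea. They form the corneal endothelium, the monolayer on its inner face that controls hydration, and then the keratocytes, the fibroblasts of its stroma. The comparisons ask which transcripts differ between the migratory population and the corneal tissues it forms, and between the endothelium and the later tissue that also holds stromal cells. The deposited expected counts summed to 18405559, 19999902 and 22055958 in the E3 libraries. They summed to 23205388, 22879457 and 18815844 in the libraries labelled E5, and to 9874339, 13740392 and 11376153 in those labelled E7. The labels do not say whether the 3 libraries of a group came from separate embryos or dissections, so the p-values measure only the spread between these samples, which may be technical.

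The E3 libraries lay close together, and the 6 corneal libraries lay apart from them but did not separate by their labels. Pearson correlations of log2(CPM + 1) across genes, which are not independent replicates, were 0.987 to 0.988 among the E3 libraries and 0.872 to 0.904 between these and all others. E7 library 3 correlated with E5 libraries 1 and 2 at 0.985 and 0.981, and with E7 libraries 1 and 2 at 0.926 and 0.937. E5 library 3 correlated with E7 libraries 1 and 2 at 0.975 and 0.981, and with E5 libraries 1 and 2 at 0.942 and 0.948. The second principal component, with 24% of the variance, placed E5 libraries 1 and 2 at 36.3 and 31.8 and E7 library 3 at 34.4, against -35.1 for E5 library 3 and -51.4 and -40.5 for E7 libraries 1 and 2. No pair of libraries of a group agreed within sampling noise, since the chi-square per degree of freedom ran from 9.88 to 146.56.

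**Figure D1:**
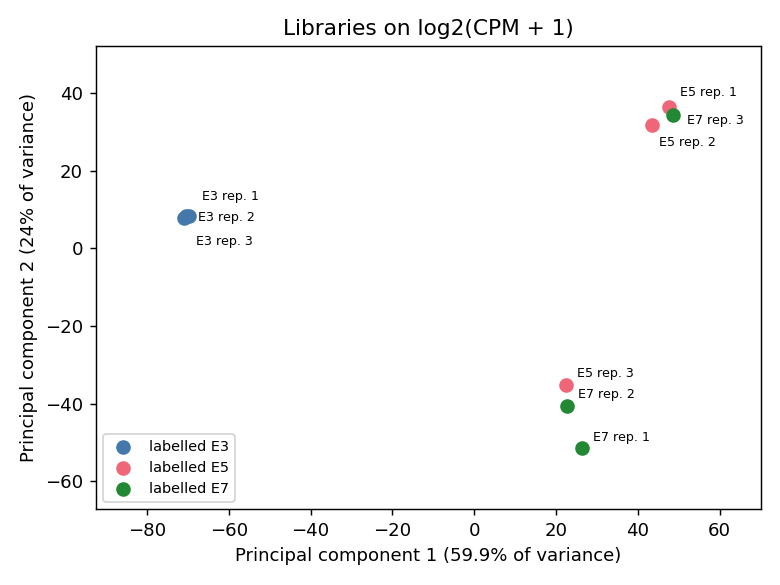
Principal components of log2(CPM + 1) for the 9 libraries, with the share of variance on each axis and colours for the labelled stage. The first component, with 59.9% of the variance, separates E3 from the other libraries, and the second places E7 library 3 (34.4) beside E5 libraries 1 and 2 (36.3 and 31.8).

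From E3 periocular neural crest to E5 corneal endothelium, many transcripts of the corneal matrix and that of the water channel AQP1 rose, and several of migratory neural crest, such as SOX10, fell. AQP1 (gene ID 420384) rose from 0.903 ± 0.376 to 894 ± 321 FPKM (mean ± SD, n = 3 in each group here and throughout), a log2 fold change of 10.11 ± 0.63 (estimate ± SE, adjusted p = 2.61e-05, edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment, as for every adjusted p of a gene below unless another tool is named). KERA (373995), which encodes the corneal proteoglycan keratocan, rose from 23.5 ± 4.62 to 1363 ± 662 FPKM (log2 fold change 6.24 ± 0.68, adjusted p = 0.000464). SOX10 (395573), a factor of migratory crest and glia, fell from 16.1 ± 1.44 to 0.183 ± 0.300 FPKM (-6.41 ± 1.21, adjusted p = 0.00505). Its E5 value rested on library 3 (0.53 against 0.01 and 0.01 FPKM in the other two), without which the log2 fold change was -10.06 (adjusted p = 0.000662).

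Of 11748 genes tested, 2172 were higher and 2077 lower at E5 than at E3, 36.2% of the genes, and 1219 and 677 of them changed by a log2 fold change of 1 or more. In 6393 genes (54.4%) every library of one group lay above every library of the other, where chance gives 10%. The counts fell to 1428 higher and 1334 lower without E3 library 2, to 1424 and 1354 without E3 library 3, and to 1351 lower without E5 library 1. The median log2 fold change over all genes was 0.03 with TMM factors and 51.1% of the calls were higher. Scaled by library size alone it was -0.14 with 35.9% of the calls higher, and limma on log2(FPKM + 1) gave -0.15 and 32.6%, so changes near these shifts depend on the scaling.

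The largest rises among well expressed genes were those of GHRHR, AQP1, COL6A2, FNDC1, MMP27 and C4ORF19. FNDC1 (421589) rose from 0.187 ± 0.0150 to 167 ± 30.7 FPKM (9.95 ± 0.26, adjusted p = 4.63e-07). MMP27 (395850), a matrix metalloproteinase, rose from 0.0630 ± 0.00600 to 29.1 ± 10.6 FPKM (8.94 ± 0.51, adjusted p = 1.91e-05). C4ORF19 (101747284) rose from 0.123 ± 0.0900 to 53.4 ± 9.62 FPKM (8.93 ± 0.39, adjusted p = 6.3e-06). COL6A2 (396292), a chain of type VI collagen, stood at 0.613 ± 0.0550 FPKM at E3 and at 895, 796 and 56.2 FPKM in E5 libraries 1, 2 and 3 (10.09 ± 1.89, adjusted p = 0.00486). GHRHR (420385), the receptor for growth hormone-releasing hormone, had 0 counts at E3 and 5085 at E5, at least 1580-fold higher against a floor of 3 counts over the group. Its FPKM was 66.9, 65.6 and 3.40 in the E5 libraries, and its adjusted p of 0.0268 passed 0.05 when any E3 library or E5 library 1 or 2 was left out, up to 0.0654. The largest falls among well expressed genes were those of LIN28A, CER1, FOXL2, FOXD1 and the globin genes HBZ and HBBR. LIN28A (428206), an RNA-binding protein of early embryonic cells, fell from 40.0 ± 9.36 to 0.0530 ± 0.0210 FPKM (-9.29 ± 0.45, adjusted p = 9.95e-06). FOXL2 (503512) fell from 29.4 ± 4.59 to 0.103 ± 0.0960 FPKM (-7.96 ± 0.68, adjusted p = 0.00014). FOXD1 (396109) fell from 15.3 ± 0.727 to 0.0670 ± 0.0640 FPKM (-7.69 ± 0.55, adjusted p = 5.5e-05). CER1 (395623), a secreted antagonist of BMP and Nodal ligands, had 874 counts at E3 and 2 at E5, a ratio of 469 (95% counting interval 129 to 3880, adjusted p = 0.00053).

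**Figure D2:**
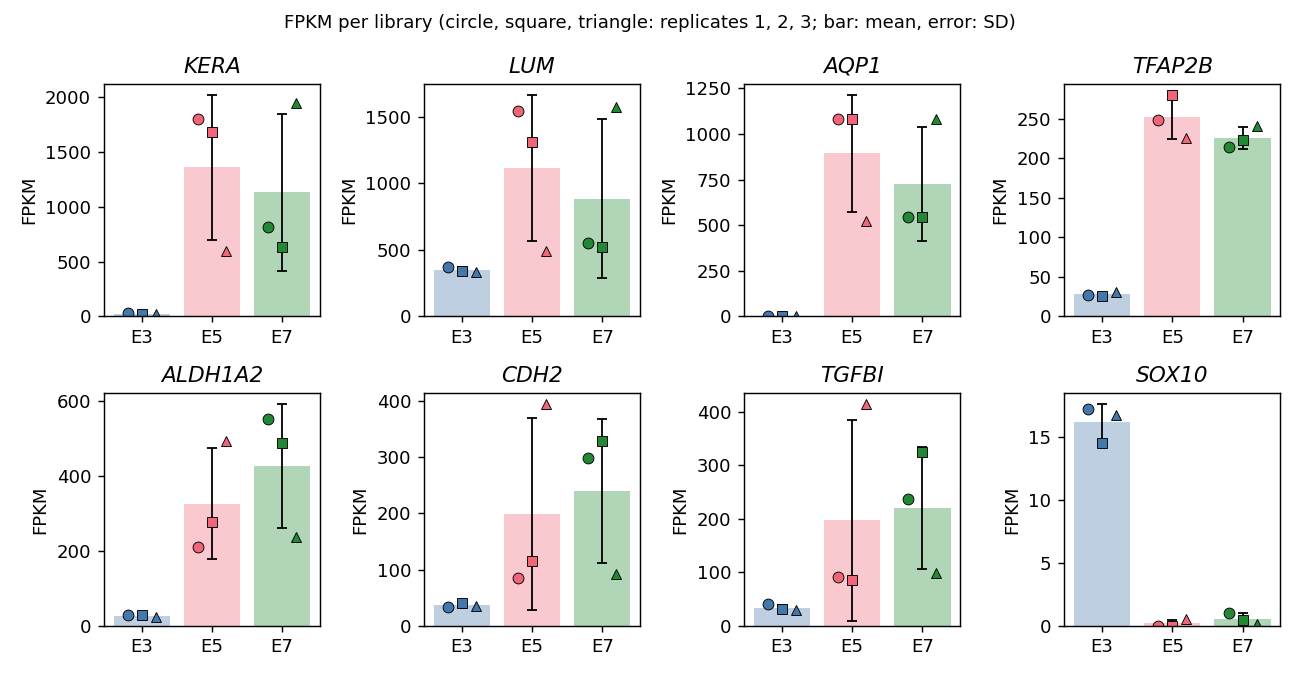
FPKM per library of KERA, LUM, AQP1, TFAP2B, ALDH1A2, CDH2, TGFBI and SOX10 in the libraries labelled E3, E5 and E7, on linear axes from 0, with symbols for the replicate numbers, bars for the means and error bars for the SD (n = 3). KERA stood at 601 FPKM in E5 library 3 and at 1803 and 1685 in the other E5 libraries, and at 1952 in E7 library 3 and at 816 and 632 in the other E7 libraries.

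Genes of the corneal stroma rose together. Of 19 measured genes for stromal proteoglycans and keratan sulfate synthesis, 14 rose and none fell, and 14 and 0 did so adjusted over the list alone (camera, higher, adjusted p = 3.62e-06; adjusted p = 0.342 with an estimated correlation). OGN, osteoglycin, rose from 3.95 ± 0.965 to 721 ± 431 FPKM (7.71 ± 0.95, adjusted p = 0.000795). DCN, decorin, rose from 92.6 ± 9.12 to 1144 ± 645 FPKM (3.83 ± 0.67, adjusted p = 0.00375). LUM, lumican, rose from 350 ± 20.8 to 1116 ± 552 FPKM (1.87 ± 0.56, adjusted p = 0.032), a call lost without any E3 library or E5 library 1 or 2, at up to 0.0999. The summed level of this list was 14936, 13360 and 4752 CPM in E5 libraries 1, 2 and 3, and 1292 to 1427 CPM at E3. Of 20 collagens, 14 rose and 1 fell, as adjusted over the list alone (camera, higher, adjusted p = 1.45e-05; adjusted p = 0.197 with an estimated correlation). COL6A1 rose from 1.69 ± 0.243 to 183 ± 126 FPKM (6.97 ± 1.38, adjusted p = 0.00614). COL16A1 rose from 2.78 ± 0.0960 to 71.0 ± 40.8 FPKM (4.87 ± 0.68, adjusted p = 0.00138). COL9A3 fell from 6.03 ± 0.268 to 1.29 ± 0.0870 FPKM (-2.05 ± 0.23, adjusted p = 0.000488). Of 19 genes for collagen processing and crosslinking, 14 rose and 2 fell, and 16 and 2 adjusted over the list alone (camera, higher, adjusted p = 3.3e-07; adjusted p = 0.197 with an estimated correlation). PLOD2, a lysyl hydroxylase, rose from 29.4 ± 1.44 to 189 ± 36.4 FPKM (2.86 ± 0.15, adjusted p = 1.62e-05). P4HA3, a prolyl hydroxylase subunit, rose by a log2 fold change of 4.73 ± 0.56 (adjusted p = 0.000627).

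Hyaluronan and matrix remodelling genes rose in 10 of 22 and fell in 2, and 11 and 2 adjusted over the list alone (camera, higher, adjusted p = 0.000163; adjusted p = 0.0654 with an estimated correlation). HAS2, a hyaluronan synthase, rose from 20.4 ± 0.206 to 158 ± 22.0 FPKM (3.13 ± 0.13, adjusted p = 4.43e-06). THBS1, thrombospondin 1, rose from 11.9 ± 0.920 to 88.4 ± 26.1 FPKM (3.06 ± 0.21, adjusted p = 4.75e-05). TGFBI rose to 197 ± 188 FPKM (2.71 ± 0.66, adjusted p = 0.0146), a value that fell to 1.62 without E5 library 3, and the call was lost without E3 library 2 or 3, at up to 0.0589. Basement membrane genes went both ways, with 7 of 23 up and 4 down, as adjusted over the list alone (camera adjusted p = 0.521). SPARC rose from 210 ± 9.95 to 1310 ± 383 FPKM (2.83 ± 0.36, adjusted p = 0.000891). LAMA5 rose from 2.62 ± 0.391 to 11.9 ± 1.96 FPKM (2.36 ± 0.17, adjusted p = 6.12e-05). NID2 fell from 47.5 ± 4.80 to 22.9 ± 1.93 FPKM (-0.88 ± 0.17, adjusted p = 0.00554).

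Neural crest genes and periocular transcription factors each included genes that rose and genes that fell. Of 30 neural crest genes, 7 rose and 12 fell, and 8 and 15 adjusted over the list alone (camera, lower, adjusted p = 0.154, and 0.0325 without E3 library 2 and 0.0445 without E7 library 2; adjusted p = 0.502 with an estimated correlation). FOXD3, a crest specifier, fell from 9.26 ± 1.32 to 0.0700 ± 0.0620 FPKM (-6.89 ± 0.98, adjusted p = 0.00152). PAX3 fell from 16.2 ± 1.89 to 0.18 ± 0.144 FPKM (-6.34 ± 0.85, adjusted p = 0.00116). The AP-2 factor TFAP2B rose from 27.7 ± 2.32 to 252 ± 27.3 FPKM (3.49 ± 0.15, adjusted p = 6.1e-06). TFAP2E, another, rose from 9.97 ± 2.72 to 111 ± 5.14 FPKM (3.65 ± 0.21, adjusted p = 1.91e-05). TFAP2A stood at 19.5 ± 1.58 and 9.90 ± 6.93 FPKM (adjusted p = 0.253, and 0.0383 without E5 library 3) and TWIST1 at 75.7 ± 12.1 and 77.2 ± 18.4 FPKM (adjusted p = 0.619). SNAI2 rose from 21.7 ± 1.33 to 27.9 ± 5.94 FPKM (0.55 ± 0.17, adjusted p = 0.0356), with 0.34 without E5 library 1, and the call was lost without any E3 library, E5 library 1 or 2 or E7 library 1, at up to 0.105. Of 23 periocular mesenchyme factors, 4 rose and 12 fell, as adjusted over the list alone (camera, lower, adjusted p = 0.000501; adjusted p = 0.252 with an estimated correlation). LMX1B rose from 43.4 ± 3.69 to 133 ± 58.0 FPKM (1.78 ± 0.30, adjusted p = 0.00324). SIX2 fell from 37.7 ± 5.06 to 0.323 ± 0.473 FPKM (-6.78 ± 1.13, adjusted p = 0.00301). EYA2 fell from 45.2 ± 3.93 to 1.05 ± 0.515 FPKM (-5.31 ± 0.40, adjusted p = 7.51e-05). ALX4 fell from 127 ± 16.0 to 62.8 ± 2.36 FPKM (-0.84 ± 0.14, adjusted p = 0.00292).

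Among 26 genes of the endothelial pump, transport and junctions, 6 rose and 4 fell, and 7 and 4 adjusted over the list alone (camera adjusted p = 0.278). Besides AQP1, COL8A2, a collagen of Descemet's membrane, rose from 7.58 ± 1.03 to 76.1 ± 10.9 FPKM (3.51 ± 0.29, adjusted p = 0.000128). CDH2, N-cadherin, stood at 84.6, 116 and 395 FPKM in the E5 libraries and at 36.0 ± 3.67 at E3 (2.61 ± 0.63, adjusted p = 0.0141). Its value fell to 1.68 without E5 library 3, and its call was lost without any E3 library, at up to 0.0556. CA2, carbonic anhydrase 2, fell from 98.3 ± 9.88 to 1.75 ± 2.72 FPKM (-5.72 ± 1.33, adjusted p = 0.0121; -8.83 without E5 library 3). TJP1, a tight junction protein, fell from 22.8 ± 2.21 to 10.9 ± 3.82 FPKM (-0.90 ± 0.25, adjusted p = 0.0232), a call lost without any E3 library, at up to 0.0782. The sodium pump subunit ATP1B1 (17.3 ± 1.28 and 17.7 ± 10.5 FPKM, adjusted p = 0.726), SLC4A11 (1.11 ± 0.0700 and 0.763 ± 0.129 FPKM, adjusted p = 0.321), COL8A1 (1.07 ± 0.309 and 3.59 ± 2.70 FPKM, adjusted p = 0.151, and 0.0451 without E7 library 3) and PTGDS (5.94 ± 1.05 and 2.62 ± 2.04 FPKM, adjusted p = 0.271) did not pass the test.

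Of 35 WNT pathway genes, 14 rose and 7 fell, and 15 and 8 adjusted over the list alone (camera, higher, adjusted p = 0.000501, and 0.0584 with the replicate number as a block; adjusted p = 0.0654 with an estimated correlation). The ligand WNT9A rose from 0.263 ± 0.155 to 62.1 ± 4.41 FPKM (8.08 ± 0.28, adjusted p = 2.34e-06). WNT6 rose from 0.133 ± 0.1 to 43.3 ± 20.8 FPKM (8.58 ± 0.56, adjusted p = 3.83e-05). The antagonist DKK2 rose from 1.85 ± 0.501 to 197 ± 36.3 FPKM (6.91 ± 0.28, adjusted p = 4.43e-06). Of 24 FGF pathway genes, 11 rose and 2 fell, and 14 and 3 adjusted over the list alone (camera, higher, adjusted p = 0.0287; adjusted p = 0.197 with an estimated correlation). FGF16 rose from 0.140 ± 0.135 to 21.1 ± 4.04 FPKM (7.31 ± 0.65, adjusted p = 0.000173), FGF9 had 3 counts at E3 and 1302 at E5, a ratio of 404 (138 to 1960). The receptor FGFR2 fell from 130 ± 15.4 to 15.1 ± 8.37 FPKM (-2.95 ± 0.43, adjusted p = 0.00176). TGF-beta and BMP genes split, with 8 of 30 up and 9 down, as adjusted over the list alone (camera adjusted p = 0.983). TGFB2 rose from 2.12 ± 0.208 to 63.4 ± 13.3 FPKM (5.07 ± 0.16, adjusted p = 2.01e-06). BMP5 fell from 8.27 ± 1.19 to 0.203 ± 0.144 FPKM (-5.32 ± 0.60, adjusted p = 0.000531).

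In the retinoic acid pathway 6 of 17 genes rose and 4 fell, as adjusted over the list alone (camera adjusted p = 0.219). ALDH1A2, which makes retinoic acid, rose from 26.9 ± 4.01 to 326 ± 148 FPKM (3.76 ± 0.38, adjusted p = 0.000341). The binding protein CRABP1 fell from 593 ± 63.4 to 28.2 ± 15.5 FPKM (-4.20 ± 0.75, adjusted p = 0.00405). Of 40 axon and cell guidance genes, 12 rose and 9 fell, and 13 and 10 adjusted over the list alone (camera adjusted p = 0.599). SLIT2 rose from 4.66 ± 0.730 to 20.6 ± 0.803 FPKM (2.32 ± 0.14, adjusted p = 2.61e-05). The receptor EPHA3 fell from 53.4 ± 7.46 to 0.960 ± 0.760 FPKM (-5.62 ± 0.88, adjusted p = 0.00222).

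Cell cycle and DNA replication genes fell, 22 of 31 with none higher, as adjusted over the list alone (camera, lower, adjusted p = 1.54e-05; adjusted p = 0.289 with an estimated correlation). The falls were moderate. ORC1 fell from 21.6 ± 1.63 to 8.36 ± 1.52 FPKM (-1.19 ± 0.12, adjusted p = 0.00035). CCND1 fell from 72.8 ± 4.61 to 31.3 ± 5.83 FPKM (-1.03 ± 0.17, adjusted p = 0.00251). Of 26 glycolysis and hypoxia genes, 8 rose and 2 fell, and 8 and 3 adjusted over the list alone (camera adjusted p = 0.599). LDHA rose from 46.4 ± 10.1 to 308 ± 154 FPKM (2.93 ± 0.54, adjusted p = 0.00454). TPI1 fell from 520 ± 24.5 to 326 ± 36.2 FPKM (-0.50 ± 0.09, adjusted p = 0.00467). Contractile genes rose in 8 of 18 with none lower, as adjusted over the list alone (camera, higher, adjusted p = 0.00426; adjusted p = 0.601 with an estimated correlation). TAGLN rose from 4.45 ± 0.769 to 90.1 ± 69.7 FPKM (4.49 ± 0.62, adjusted p = 0.00135). The summed level of the contractile list was 4153, 4280 and 7405 CPM in E5 libraries 1, 2 and 3 and 4256 to 4526 CPM at E3.

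Markers of other cell types moved as well. All 9 measured erythroid genes fell, as adjusted over the list alone (camera, lower, adjusted p = 0.000119; adjusted p = 0.306 with an estimated correlation), and their summed level was 2876 to 3355 CPM at E3 against 9.90, 5.10 and 50.1 CPM in the E5 libraries. HBZ fell from 2850 ± 165 to 11.9 ± 18.4 FPKM (-7.81 ± 1.86, adjusted p = 0.0132). HBBR fell from 2255 ± 323 to 11.6 ± 16.8 FPKM (-7.50 ± 1.65, adjusted p = 0.00955); globin genes resemble each other and may share reads, so values of single members are uncertain. Of 20 vascular endothelial genes, 11 fell and 2 rose, and 14 and 2 adjusted over the list alone (camera, lower, adjusted p = 0.0011; adjusted p = 0.359 with an estimated correlation). Their summed level was 989, 1022 and 1096 CPM in the E3 libraries and 722, 818 and 1219 CPM in the E5 libraries. A sum follows the most abundant members. The mean level per gene, on log2(CPM + 1) as a difference from the mean of all 9 libraries, was 1.54 to 1.73 at E3. It was -1.22, -1.14 and -0.25 in the E5 libraries. KDR fell from 14.2 ± 1.34 to 0.483 ± 0.734 FPKM (-4.78 ± 1.17, adjusted p = 0.0147; -7.64 without E5 library 3). FLT4 rose from 9.70 ± 1.30 to 65.8 ± 25.0 FPKM (2.93 ± 0.27, adjusted p = 0.000208). ERG rose from 16.5 ± 1.64 to 62.0 ± 13.1 FPKM (1.71 ± 0.32, adjusted p = 0.00459). Of 13 leukocyte genes, 5 fell, as adjusted over the list alone, with RAC2 at 4.38 ± 0.105 and 0.867 ± 0.376 FPKM (-2.17 ± 0.49, adjusted p = 0.0104). The other called members were LAPTM5, PTPRC, C1QA and C1QC. The call of LAPTM5 was lost whichever of the 9 libraries was left out except E5 library 3, at up to 0.129. Those of PTPRC (without E3 library 2 or 3, E5 library 1 or 2, or E7 library 1 or 2), C1QC (any E3 library, E5 library 1 or 2, or E7 library 1 or 2) and C1QA (any E3 library, E5 library 1 or 2, or E7 library 2) were lost at up to 0.16, 0.14 and 0.114. The leukocyte list gave a camera adjusted p of 0.0762, and of 0.0294, 0.0325 and 0.0422 without E3 library 1, 2 or 3, 0.0176 without E5 library 3, 0.0493 without E7 library 1 and 0.0307 with the replicate number as a block.

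Epithelial genes rose in 7 of 24 with none lower, as adjusted over the list alone (camera, higher, adjusted p = 0.0922). That value was 0.0299 and 0.0422 without E3 library 1 or 3, and 0.02 and 0.00696 without E5 library 1 or 2. It was 0.0239 scaled by library size alone and 0.0344 with the replicate number as a block. The rise of the list as a whole lay in E5 library 3. The summed epithelial level was 123, 95.2 and 602 CPM in E5 libraries 1, 2 and 3 and 107 to 112 CPM at E3. The mean level per gene was -0.66, -0.81 and 1.06 in these E5 libraries and -0.82 to -0.75 at E3. COL17A1, a hemidesmosome collagen, stood at 0.623 ± 0.150 FPKM at E3 and at 5.77, 4.05 and 22.8 FPKM in the E5 libraries (4.26 ± 0.90, adjusted p = 0.00815). Of 12 neuronal genes, 5 fell, as adjusted over the list alone (camera, lower, adjusted p = 0.0287, and 0.0508 without E7 library 3; adjusted p = 0.197 with an estimated correlation). NEFM fell from 4.38 ± 0.522 to 0.347 ± 0.310 FPKM (-3.43 ± 0.61, adjusted p = 0.00398), STMN2 had 144 counts at E3 and 0 at E5, at least 51.5-fold lower (call lost with the replicate number as a block, 0.0626), and ISL1 had 102 counts and 1, a ratio of 109 (19.2 to 4370). NEFL fell as well (-2.21 ± 0.43, adjusted p = 0.00565), and so did ELAVL4 (-0.79 ± 0.20, adjusted p = 0.0175), whose call was lost without E3 library 1 or E5 library 2, at up to 0.0604. Of 6 Schwann cell and glial genes, 3 fell, among them SOX10 and CDH19, and 5 fell adjusted over the list alone (camera, lower, adjusted p = 0.0404; adjusted p = 0.349 with an estimated correlation); scaled by library size alone the neuronal and glial lists were not called (0.0764 and 0.105). The summed glial level was 140 to 154 CPM at E3 and 30, 34.2 and 293 CPM in E5 libraries 1, 2 and 3. In library 3 the sum stood above E3, but the mean level per gene, -0.02 against 0.95 to 1, stood below it. CDH19 had 47 counts at E3 and 3 at E5, a ratio of 16.8 (5.41 to 84.5), with a log2 fold change of -3.66, and -6.69 without E5 library 3. Its call was lost without any E3 library, E5 library 1 or 2 or E7 library 1, at up to 0.106. Of 8 skeletal myogenic genes, CHRNA1 rose and MYF5, TNNC1, TNNC2 and TNNI1 fell, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.406). MYF5 had 99 counts at E3 and 3 at E5, a ratio of 35.4 (11.8 to 175), with a log2 fold change of -4.75, and -7.78 without E5 library 3. Its call was lost without E5 library 1 (0.0507). The call of TNNI1 was lost without any E3 library, E5 library 1 or 2 or E7 library 2, at up to 0.126, and that of TNNC1 without any library but E7 library 3, at up to 0.146. Of 14 cartilage genes, 2 rose and 6 fell, and 3 and 6 adjusted over the list alone (camera adjusted p = 0.278), with SOX9 lower at 0.933 ± 0.286 than at 10.6 ± 3.16 FPKM (-3.30 ± 0.41, adjusted p = 0.00084). The 2 that rose were EPYC and COL2A1, and COL2A1 stood at 84.4 ± 7.77 FPKM at E3 and at 305, 178 and 857 FPKM in the E5 libraries (2.55 ± 0.69, adjusted p = 0.0226). Its value was 1.73 without E5 library 3, and its call was lost without that library or any E3 library, at up to 0.0808, and with the replicate number as a block (0.0629). The summed cartilage level was higher at E5, with 1616, 999 and 4244 CPM against 501 to 586 CPM at E3. The mean level per gene was not, at -0.06, -0.27 and -0.28 against -0.01 to 0.3 at E3. Of 7 neural retina genes only SFRP1 was called, lower, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.176, and 0.0333, 0.0285 and 0.0276 without E5 library 2, E7 library 1 or E7 library 2). Of 14 pigment cell genes BEST1 rose and RAB38 fell, with 0 and 1 adjusted over the list alone (camera adjusted p = 0.92; the call of BEST1 was lost without any E3 library or E5 library 1, at up to 0.104). Of 3 lens genes CRYBA1 rose, as adjusted over the list alone (camera adjusted p = 0.92).

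**Figure D3:**
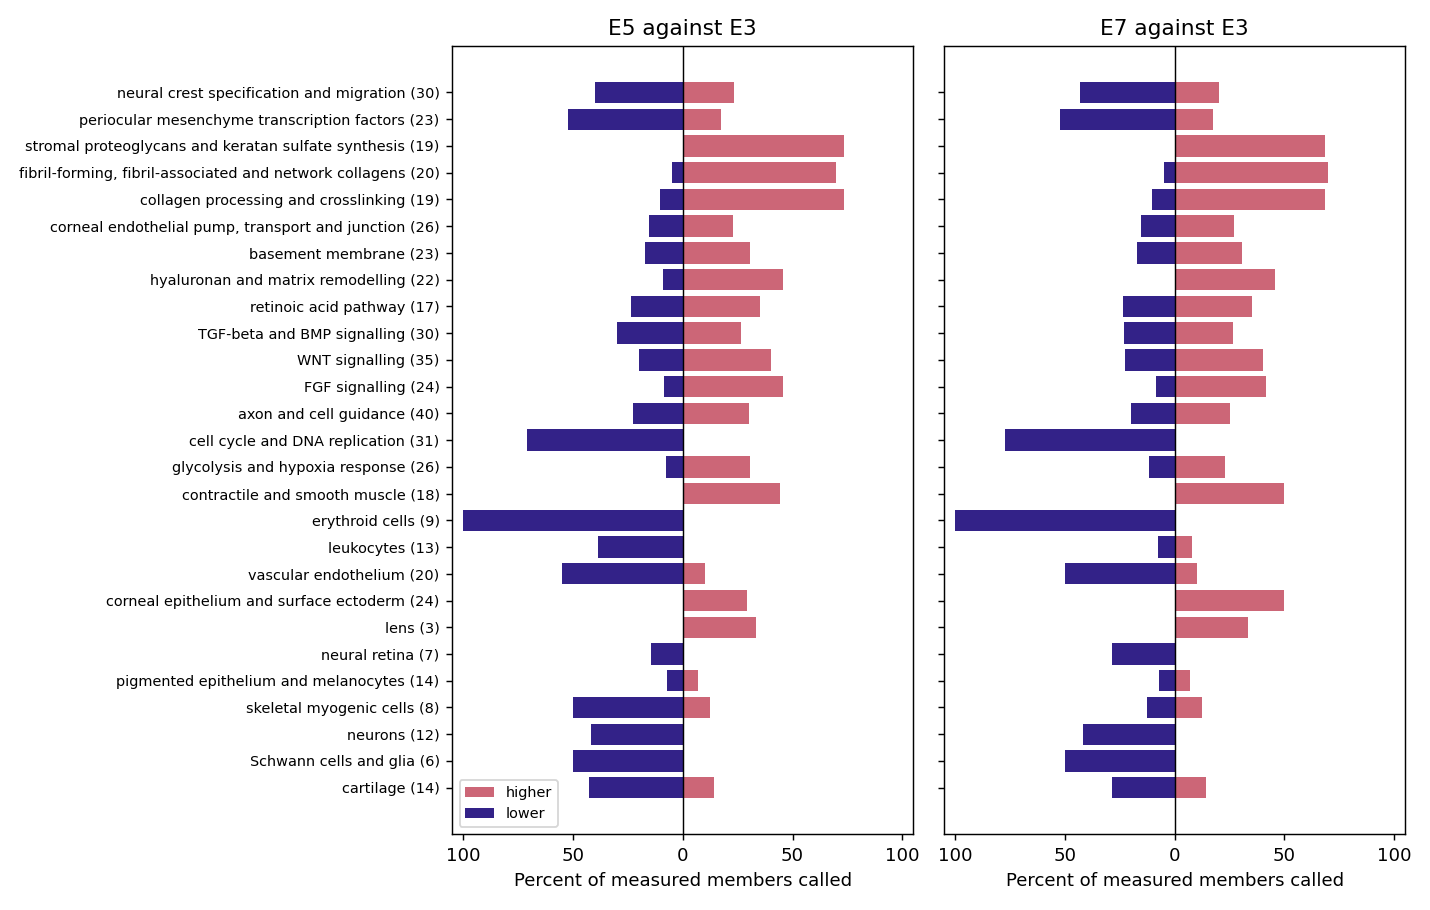
Percent of the measured members of each gene list (their number in brackets) called higher, to the right, or lower, to the left, in E5 against E3 and in E7 against E3 (edgeR, adjusted p under 0.05 over all genes). In both, 14 of 20 collagens were higher and all 9 erythroid genes were lower.

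The E7 tissue, corneal endothelium with keratocytes, differed from E3 periocular neural crest in many of the same genes. KERA stood at 1133 ± 715 FPKM (log2 fold change 5.93 ± 0.67, adjusted p = 0.000557) and AQP1 at 726 ± 311 FPKM (9.77 ± 0.62, adjusted p = 3.07e-05). SOX10 fell to 0.517 ± 0.454 FPKM (-4.83 ± 1.12, adjusted p = 0.0124). PAX3 fell to 0.147 ± 0.197 FPKM (-6.52 ± 0.89, adjusted p = 0.00129). WNT9B, a ligand, was at 0.0230 ± 0.00600 FPKM at E3 and 15.1 ± 15.4 at E7 (9.36 ± 2.55, adjusted p = 0.0236), a call lost without any E3 library, at up to 0.0854. In all, 2031 genes were higher and 1930 lower, 33.7% of those tested, and 1208 and 566 of them by a log2 fold change of 1 or more; the libraries of the groups did not overlap in 6272 genes (53.4%), where chance gives 10%. Leaving out E3 library 2 lowered the counts to 1329 and 1250. The median log2 fold change was 0.04 and 51.3% of the calls were higher, against -0.10 and 38.7% when scaled by library size alone and -0.11 and 34.5% with limma on log2(FPKM + 1).

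The calls of both comparisons overlapped, with 1750 genes higher and 1698 lower in both E5 and E7 than in E3, where independent lists would share 375 and 341. No gene was called in opposite directions. Unchanged groups simulated against the same E3 libraries shared 0 in each of 10 simulations. They were drawn around the mean of those E3 libraries, which removes the error that sharing them brings. That 0 is therefore no baseline for the overlap. Part of the excess may come from the E3 libraries that both comparisons share, which were too few to be split. All 6 corneal libraries lay above every E3 library in 2549 genes (21.7%) and below in 2663 (22.7%), where chance gives 1.19%.

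Among genes with a mean FPKM of 10 or more in the higher group, the largest rises at E7 were those of VIT, GHRHR, ANGPTL7, AQP1, HSD17B2 and FNDC1. VIT (421471), vitrin, a matrix protein, had 0 counts at E3 and 3344 at E7, at least 1930-fold higher, with 42.2, 26.4 and 0.22 FPKM in E7 libraries 1, 2 and 3 (adjusted p = 0.0395). GHRHR, with 0 counts at E3 and 1432 at E7, was at least 825-fold higher and showed the reverse order, 2.30, 3.22 and 71.2 FPKM (adjusted p = 0.0356). ANGPTL7 (101750033), a secreted protein of the corneal stroma, rose from 0.0170 ± 0.0150 to 24.9 ± 22.9 FPKM (10.65 ± 2.14, adjusted p = 0.00692). FNDC1 rose to 128 ± 18.8 FPKM (9.54 ± 0.25, adjusted p = 5.21e-07), and HSD17B2 (415807), a steroid dehydrogenase, to 16.8 ± 16.8 FPKM (9.70 ± 2.28, adjusted p = 0.0132). The calls of VIT and HSD17B2 were lost without any E3 library, at up to 0.0907 and 0.055, that of VIT also without E7 library 1 or 2, and that of GHRHR without any E3 library, E5 library 1 or 2 or E7 library 3, at up to 0.082. The largest falls with the same limit on FPKM were those of LIN28A, with 3650 counts at E3 and 1 at E7 (ratio 2110, 379 to 83500), CER1 (874 counts and 1, ratio 506, 90.5 to 20000), FOXD1 (-7.27 ± 0.55, adjusted p = 8.11e-05), the guidance receptor EPHA4 (-6.54 ± 1.12, adjusted p = 0.0035), PAX3, and FOXL2 (-6.21 ± 0.62, adjusted p = 0.000309).

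Stromal matrix genes were higher at E7 as well. Of 19 genes for stromal proteoglycans and keratan sulfate synthesis 13 rose and none fell, and 14 and 0 adjusted over the list alone (camera, higher, adjusted p = 1.21e-05; adjusted p = 0.403 with an estimated correlation). OGN rose to 516 ± 452 FPKM (7.20 ± 0.93, adjusted p = 0.00102). DCN rose to 958 ± 650 FPKM (3.54 ± 0.66, adjusted p = 0.0051). LUM stood at 884 ± 598 FPKM (1.51 ± 0.55, adjusted p = 0.0673, and 0.0323 without E5 library 3). DESeq2 called LUM higher, but it called 60 unchanged genes in the simulated data of this comparison, where edgeR called 8, so that call may be false. The summed level of this list was 6040, 4998 and 15574 CPM in E7 libraries 1, 2 and 3. Of 20 collagens 14 rose and 1 fell, and 15 and 1 adjusted over the list alone (camera, higher, adjusted p = 6.05e-06; adjusted p = 0.215 with an estimated correlation). Of 19 collagen processing genes 13 rose and 2 fell, and 15 and 2 adjusted over the list alone (camera, higher, adjusted p = 1.66e-07; adjusted p = 0.215 with an estimated correlation). COL6A2 stood at 41.3, 53.3 and 874 FPKM in the E7 libraries (9.23 ± 1.83, adjusted p = 0.00658). COL6A1 rose by 6.27 ± 1.33 (adjusted p = 0.00879) and by 4.02 without E7 library 3. Hyaluronan and matrix remodelling genes rose in 10 of 22, with 11 adjusted over the list alone and none lower (camera, higher, adjusted p = 0.000101; adjusted p = 0.0699 with an estimated correlation). ADAMTS5 rose from 0.207 ± 0.0380 to 5.98 ± 2.56 FPKM (4.97 ± 0.44, adjusted p = 0.000159). TGFBI rose to 220 ± 115 FPKM (2.84 ± 0.66, adjusted p = 0.0129), a call lost without E3 library 2 or 3, at up to 0.0537. Basement membrane genes again split, 7 of 23 up and 4 down, and 7 and 5 adjusted over the list alone (camera adjusted p = 0.304). COL4A4, a type IV collagen chain, had 0 counts at E3 and 1128 at E7, at least 650-fold higher, and LAMA4 fell from 22.4 ± 0.445 to 0.780 ± 0.876 FPKM (-4.67 ± 0.95, adjusted p = 0.00741).

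Of 30 neural crest genes 6 rose and 13 fell at E7, and 8 and 14 adjusted over the list alone (camera adjusted p = 0.24). Of 23 periocular factors 4 rose and 12 fell, as adjusted over the list alone (camera, lower, adjusted p = 0.00066; adjusted p = 0.362 with an estimated correlation). SIX2 fell to 0.613 ± 0.605 FPKM (-5.83 ± 1.09, adjusted p = 0.00503). FOXD3 fell to 0.110 ± 0.149 FPKM (-6.31 ± 0.98, adjusted p = 0.00231). ALX4 fell to 60.1 ± 9.01 FPKM (-0.94 ± 0.14, adjusted p = 0.00189). LMX1B rose to 147 ± 46.4 FPKM (1.89 ± 0.30, adjusted p = 0.00263). TFAP2B rose to 226 ± 14.0 FPKM (3.26 ± 0.15, adjusted p = 7.46e-06). SNAI2 stood at 27.1 ± 1.65 FPKM against 21.7 ± 1.33 at E3 (0.46 ± 0.17, adjusted p = 0.0674, and 0.0181 and 0.0356 without E5 library 1 or 3). DESeq2 called SNAI2 higher, with the limit given for LUM. Of 26 pump, transport and junction genes 7 rose and 4 fell, as adjusted over the list alone (camera adjusted p = 0.284), with COL8A2 at 74.4 ± 26.7 FPKM (3.45 ± 0.29, adjusted p = 0.000137) and CDH2 at 240 ± 129 FPKM (2.85 ± 0.64, adjusted p = 0.0107). CA2 fell to 3.53 ± 2.96 FPKM (-4.69 ± 1.27, adjusted p = 0.0231), a call lost without any E3 library or E7 library 1 or 2, at up to 0.0625. TJP1 fell to 10.8 ± 2.07 FPKM (-0.95 ± 0.25, adjusted p = 0.0198), a call lost without E3 library 2 or E7 library 2 or 3, at up to 0.0699. ATP1B1, SLC4A11, COL8A1, PTGDS, TFAP2A and TWIST1 had adjusted p-values of 0.579, 0.16, 0.192, 0.505, 0.832 and 0.684. In the retinoic acid pathway 6 of 17 genes rose and 4 fell, and 8 and 4 adjusted over the list alone (camera adjusted p = 0.113, and 0.0482 without E7 library 3), with ALDH1A2 at 426 ± 166 FPKM (4.11 ± 0.39, adjusted p = 0.000242).

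WNT genes were higher in 14 of 35 and lower in 8 at E7, and in 18 and 9 adjusted over the list alone (camera, higher, adjusted p = 0.00062, and 0.0894 with the replicate number as a block; adjusted p = 0.0699 with an estimated correlation), with WNT9A at 67.4 ± 7.90 FPKM (8.15 ± 0.28, adjusted p = 2.21e-06). LEF1, a nuclear effector of the pathway, fell from 12.6 ± 2.60 to 4.56 ± 0.594 FPKM (-1.33 ± 0.21, adjusted p = 0.00234). FGF genes rose in 10 of 24 and fell in 2, as adjusted over the list alone (camera, higher, adjusted p = 0.0253; adjusted p = 0.215 with an estimated correlation), with FGF7 up from 2.08 ± 1.82 to 15.3 ± 6.42 FPKM (3.13 ± 0.68, adjusted p = 0.00935). TGF-beta and BMP genes rose in 8 of 30 and fell in 7, and in 8 and 9 adjusted over the list alone (camera adjusted p = 0.807). Guidance genes rose in 10 of 40 and fell in 8, and in 11 and 8 adjusted over the list alone (camera adjusted p = 0.618). Cell cycle genes fell in 24 of 31 with none higher, and in 25 adjusted over the list alone (camera, lower, adjusted p = 4.83e-07; adjusted p = 0.215 with an estimated correlation), with ORC1 at 9.12 ± 0.586 FPKM (-1.10 ± 0.12, adjusted p = 0.000517). Glycolysis genes rose in 6 of 26 and fell in 3, as adjusted over the list alone (camera adjusted p = 0.905). Contractile genes rose in 9 of 18, and in 10 adjusted over the list alone, with none lower (camera, higher, adjusted p = 0.000611; adjusted p = 0.495 with an estimated correlation). TAGLN rose to 113 ± 55.3 FPKM (4.78 ± 0.63, adjusted p = 0.00112), and the summed contractile level was 7458, 7268 and 4064 CPM in E7 libraries 1, 2 and 3.

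Among markers of other cell types at E7, all 9 erythroid genes fell, as adjusted over the list alone (camera, lower, adjusted p = 0.000195; adjusted p = 0.403 with an estimated correlation), with a summed level of 199, 36.7 and 10.6 CPM in the E7 libraries. HBAD fell from 639 ± 34.1 to 16.8 ± 16.1 FPKM (-5.16 ± 1.04, adjusted p = 0.00707). Vascular genes fell in 10 of 20 and rose in 2, and in 14 and 2 adjusted over the list alone (camera, lower, adjusted p = 0.00125; adjusted p = 0.403 with an estimated correlation), with summed levels of 946, 1125 and 732 CPM in the E7 libraries and FLT4 again higher (3.00 ± 0.27, adjusted p = 0.000188). The mean level per vascular gene was -0.71, -0.26 and -1.24 in the E7 libraries, against 1.54 to 1.73 at E3. Epithelial genes rose in 12 of 24, and in 13 adjusted over the list alone, with none lower (camera, higher, adjusted p = 0.00141; adjusted p = 0.543 with an estimated correlation). COL17A1 rose to 27.0 ± 20.9 FPKM (5.54 ± 0.95, adjusted p = 0.00345), and the summed epithelial level was 1342, 723 and 146 CPM in E7 libraries 1, 2 and 3, against 123, 95.2 and 602 CPM in the E5 libraries and 107 to 112 CPM at E3. Neuronal genes fell in 5 of 12 (STMN2, ISL1, NEFM, NEFL and ELAVL4), as adjusted over the list alone (camera, lower, adjusted p = 0.0482, and 0.0739 and 0.0593 without E7 library 2 or 3, 0.0502 with RLE factors and 0.105 scaled by library size alone; adjusted p = 0.215 with an estimated correlation). The call of STMN2 was lost with the replicate number as a block (0.0745). The calls of NEFL (without any E3 library or E7 library 2 or 3) and ELAVL4 (without E3 library 1 or E7 library 1) were lost at up to 0.0873 and 0.0577. Of the 6 glial genes 3 fell, among them SOX10 and CDH19, as adjusted over the list alone (camera adjusted p = 0.113). Their summed level was 285, 267 and 30 CPM in E7 libraries 1, 2 and 3. Their mean level per gene was 0.24, -0.08 and -0.98 in these libraries, below the 0.95 to 1 at E3. The call of CDH19 (log2 fold change -4.30, and -6.77 without E7 library 1) was lost without any E3 or E7 library, at up to 0.117. That list was called without E3 library 3 (0.0348), without E5 library 1, 2 or 3 (0.0468, 0.0243 and 0.0459) and without E7 library 1 (0.0353). Of 13 leukocyte genes CD74 rose and RAC2 fell, with none adjusted over the list alone (camera adjusted p = 0.394), and both calls were lost without any E3 library, at up to 0.0759 and 0.0902, that of CD74 also without E7 library 1 and that of RAC2 without E7 library 2 or 3. Cartilage genes rose in 2 of 14 and fell in 4, as adjusted over the list alone (camera adjusted p = 0.394). The 2 that rose were again EPYC and COL2A1, a collagen also laid down in the embryonic chick cornea, and COL2A1 stood at 1888, 922 and 325 FPKM in the E7 libraries (3.74 ± 0.73, adjusted p = 0.00613). The summed cartilage level was 9317, 4585 and 1707 CPM in these libraries. The mean level per gene was 0.17, 0.08 and -0.16 in them, against -0.01 to 0.3 at E3. Of 8 myogenic genes CHRNA1 rose and MYF5 fell, and 1 and 0 adjusted over the list alone (camera adjusted p = 0.905); the call of MYF5 was lost without any E3 or E7 library, at up to 0.126. SFRP1 and HES5 fell among 7 retinal genes, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.217, and 0.0407 without E7 library 1), and the call of HES5 was lost without any E3 or E7 library or E5 library 2, at up to 0.121. BEST1 rose and RAB38 fell among 14 pigment cell genes, as adjusted over the list alone (camera adjusted p = 0.432). CRYBA1 rose among 3 lens genes, as adjusted over the list alone (camera adjusted p = 0.857). The calls of BEST1 (without E3 library 1 or 2 or E7 library 2) and CRYBA1 (without E3 library 1 or 3) were lost at up to 0.0714 and 0.0574.

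Between the libraries labelled E7 and those labelled E5, no gene passed the test, and levels of the main corneal transcripts overlapped between the labels. KERA measured 1803, 1685 and 601 FPKM in the E5 libraries and 816, 632 and 1952 FPKM in the E7 libraries (log2 fold change -0.31 ± 0.54, adjusted p = 0.972). CDH2 measured 84.6, 116 and 395 FPKM at E5 and 299, 329 and 92.0 FPKM at E7 (0.24 ± 0.59, adjusted p = 0.975). ALDH1A2 measured 210, 276 and 493 FPKM at E5 and 553, 488 and 238 FPKM at E7 (0.35 ± 0.34, adjusted p = 0.972). TFAP2B, with 252 ± 27.3 and 226 ± 14.0 FPKM, did not pass the test either (-0.23 ± 0.14, adjusted p = 0.972). Every landmark gene had an adjusted p of 0.972 or more. With edgeR, 0 genes were higher and 0 lower at adjusted p under 0.05, the lowest adjusted p was 0.25, and 279 genes (2.4%) had an unadjusted p under 0.05. DESeq2 called 6 higher and 6 lower, limma on log2(FPKM + 1) none, limma with a pseudocount of 0.1 called 1 and 1, and limma with no filter on low values called 1 and 1. The libraries of the labels did not overlap in 581 genes (4.9%), where chance gives 10%. In simulated data of the same depth and 11748 genes, edgeR recovered 44 of 100 genes changed 2-fold and 73 of 100 changed 4-fold. Each simulated library was drawn independently, so the likeness of E5 and E7 libraries across their labels was not simulated. The absence of calls therefore does not show that the tissues differ little. The changed genes were drawn only from the better expressed ones, so low genes would be recovered less often. On the simulated data DESeq2 called 77 unchanged genes, limma 12 and edgeR 4. The few calls of DESeq2 may therefore be false. Those of limma may be false too, but the simulation ran limma on log2(CPM + 1) and cannot tell for the settings that gave them.

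Single genes that other settings called were chosen after their values were seen. DESeq2 called 77 unchanged genes in the simulated data of this comparison, so a call of DESeq2 given here may be false. LRRC8D, a subunit of volume-regulated anion channels, measured 0.68, 1.01 and 1.01 FPKM at E5 and 0.05, 0.02 and 0 FPKM at E7 (-5.09 ± 0.59, adjusted p = 0.25); DESeq2 called it lower (adjusted p = 1.08e-09), as did edgeR without E7 library 3 (adjusted p = 0.048). LEF1 measured 9.53 ± 1.57 and 4.56 ± 0.594 FPKM, lower in all 3 E7 libraries than in any E5 library (-1.11 ± 0.21, adjusted p = 0.972, and 0.0214 adjusted over the list alone, as 1 of 35 WNT genes; DESeq2 adjusted p = 0.00701). TRIM23 was lower without E7 library 2 (-4.05, adjusted p = 0.0125). The genes that limma called were microRNA genes, MIR7441 higher and MIR6687 lower with a pseudocount of 0.1 (adjusted p = 0.0301 for both), and MIR7441 higher and MIR1737 lower with no filter (adjusted p = 0.0394 and 0.0299).

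At the level of gene lists, camera called 5 of 29 lists higher at E7 than at E5, and none lower, with 0 called members in each of them, over all genes as over the list alone. These were the epithelial list (adjusted p = 2.16e-08), cytoplasmic ribosomal proteins (1.04e-05), leukocytes (0.000551), skeletal myogenic cells (0.00235) and pigment cells (0.0259). None held with an estimated correlation, where the adjusted p was 0.828 for each, and fry called no list (lowest adjusted p = 0.971). The ribosomal call was lost without E5 library 3 (0.104), the myogenic call without E5 library 1 or E7 library 2 (0.084 and 0.137), and the pigment cell call without E5 library 1 or 2 or E7 library 1 or 2 (0.234, 0.0512, 0.21 and 0.231) or scaled by library size alone (0.0559). The stromal proteoglycan list was not called (adjusted p = 0.0616) but was lower without E5 library 3 or E7 library 3 (0.000917 and 1.83e-05) and scaled by library size alone (0.0237). The contractile list (adjusted p = 0.18) was higher without these libraries (7.92e-05 and 0.00328). Without E5 library 3 camera also called the lists of periocular factors (0.032), basement membrane (0.0141), retinoic acid (0.0316), erythroid (0.011), vascular (0.000724) and glial genes (0.0302) higher and those of cell cycle (0.0421) and glycolysis (0.0302) lower. Without E7 library 3 it called the erythroid list higher (0.0451) and the cell cycle and glycolysis lists lower (0.0382 and 0.0496), and with the replicate number as a block the cell cycle list lower (0.0443). The remaining lists had adjusted p-values of 0.0616 or more, and none of their members other than LEF1 was called over its list alone. No gene followed any of the 4 patterns over the 3 stages that need a call at both steps. Without E7 library 3, 1 was found, and DESeq2 found 6. Simulated unchanged groups gave 0, but they were drawn around the mean of the E5 libraries they were tested against. That 0 is therefore no baseline for the patterns.

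The medians, means and tests of a few lists differed in sign. In E5 against E3 the basement membrane list had a median log2 fold change of -0.20 and a mean of 0.50 (0.37 with genes of 3 or fewer counts in a group at their bound) with camera higher, the retinoic acid list 0.26 and -0.46 (-0.31 at the bound) with camera higher, the lens list -0.29 and 0.21 with camera higher, the cartilage list 0.21 and -0.16 with camera lower, and the ribosomal list -0.01 and 0.01 with camera lower; the TGF-beta and BMP list was lower by camera and higher by fry. In E7 against E3 the TGF-beta and BMP list had 0.16 and -0.34 (-0.32 at the bound) with camera higher, the lens list -0.04 and 0.35 with camera higher, and the cartilage list -0.47 and 0.14 with camera lower, while the myogenic list was lower by camera and higher by fry. In E7 against E5 the collagens had -0.26 and -0.01 with camera higher, the periocular factors 0.08 and -0.13 (0.02 and 0.01 at the bound) with camera higher, the pump list -0.04 and 0.14 (0.11 at the bound) with camera lower, the WNT list 0.04 and 0 with camera lower, the FGF list 0 and 0.09 with camera lower, and the neuronal list -0.02 and -0.09 (0 and 0.05 at the bound) with camera higher. None of these camera tests passed the threshold. With fry, which does not compare a list with other genes, 20 and 21 of 29 lists were called in E5 and E7 against E3. Camera had not called 7 and 9 of them. Among these were neural crest (lower, fry adjusted p = 0.0204 and 0.0377) and the pump list (higher, 0.00131 and 0.0021). The epithelial list, called by camera in E7 against E3, was not called by fry (0.0523).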

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

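Of the tests in this part, only the thinning to equal depth and the splits for E5 and E7 against E3 were chosen before their results were seen. No formal test for single libraries far from the others was run, since groups of 3 are too small for it.

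Entries that matched no gene lay outside the comparisons of the report and still held differences. Tested with all entries unsummed by edgeR, 1035 of 13402 (7.7%) were called in E5 against E3, 685 higher and 350 lower, and 1045 (7.8%) in E7 against E3, 628 higher and 417 lower. In E7 against E5 none was called (lowest adjusted p = 0.114).

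The libraries labelled E5 and E7 resembled each other across their labels. The labelled split called 0 genes, and the split that sets E5 libraries 1 and 2 and E7 library 3 against the other three called 3911, which points to a structure of the samples other than their labels. The tables argue against sequencing depth, since 3648 genes were still called by that split after thinning every library to the depth of the shallowest. An exchange of labels between an E5 and an E7 library stays open, since a library out of place is seen in each group. Some values ran with the labels instead. LRRC8D and LEF1 were chosen after their values were seen, so they cannot decide for the labels. Over all genes tested, the E5 and E7 libraries did not overlap in 581 (4.9%), below the chance share given in the results. LRRC8D measured 0.68, 1.01 and 1.01 FPKM in the E5 libraries and 0.05, 0.02 and 0 FPKM in the E7 libraries, and LEF1 was lower in all 3 E7 libraries than in any E5 library. The totals did so too, with 18815844 counts in E5 library 3 and 11376153 in E7 library 3, where the other E5 libraries had 22879457 or more and the other E7 libraries 13740392 or fewer. Totals are set by library making and sequencing, so tissues exchanged before that step could leave them with the labels. The totals therefore cannot decide either. The split was found in these data. The labels cannot decide which libraries would have been exchanged, and a difference in stromal content between dissections was not tested and stays open.

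Erythroid transcripts and some of the vascular endothelial transcripts were higher at E3. All 9 measured erythroid genes, none on another list, were higher in every E3 library than in the 6 others, with HBZ at 2791, 3037 and 2722 FPKM in the E3 libraries. Of 20 vascular genes 11 were lower at E5 and 10 at E7 than at E3, with 2 higher in each. Their summed level at E3 (989 to 1096 CPM) was below that of E5 library 3 (1219 CPM) and E7 library 2 (1125 CPM). A sum follows the most abundant members. The mean level per gene on log2(CPM + 1), against the mean of all 9 libraries, was 1.54 to 1.73 at E3. It was -0.25 in E5 library 3 and -0.26 in E7 library 2. A lower share of the main cell type at E3 would raise markers of every other type alike, whereas 12 epithelial genes were higher at E7 than at E3. Epithelial cells in some E7 dissections would give this at any share of the main cell type. The count therefore cannot decide, and a lower share stays open. Blood cells in the E3 dissections stay open as an explanation of the erythroid part, since the count of 9 restates the calls and decides nothing, and so does the stage itself, which was not tested.

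Epithelial transcripts differed between libraries of the same label. Of 24 measured epithelial genes, none on another list, 21 had their highest level among the 6 corneal libraries in E7 library 1, where the sum of the other genes was highest whichever gene was set aside, and the summed level was 1342 CPM. COL17A1 stood at 5.77, 4.05 and 22.8 FPKM in the E5 libraries and at 48.2, 26.7 and 6.26 FPKM in the E7 libraries, and CDH3, chosen after its values were seen, at 12.3, 8.90 and 55.9 and at 111, 57.4 and 14.5 FPKM. Epithelial cells in some dissections stay open as a source. The count was taken after the pattern was seen, and genes regulated together would give it too. A difference in stage was not tested and stays open.

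For E5 against E3, 1 of 10 splits called as many genes as the labelled one (4249, highest other 0), and for E7 against E3 also 1 of 10 (3961, highest other 0). For E7 against E5 the labelled split called 0 genes (highest other 3911), a count that all 10 of 10 splits reach by definition, so it decides nothing. With 10 splits the share cannot be under 0.05.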

How the results depend on the processing

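Dropping the third libraries of E5 and E7 together, and testing entries unsummed, were chosen after the data had been seen. With single libraries left out, E5 against E3 gave 1424 to 2495 higher and 1334 to 2306 lower genes, E7 against E3 1329 to 2336 and 1250 to 2154, E7 against E5 0 to 0 higher and 0 to 1 lower, and the patterns over the 3 stages 0 to 1; 64.2 to 98.8% of the calls of E5 against E3 and 64.3 to 99.1% of those of E7 against E3 were kept, and none changed sign. For E5 against E3 and E7 against E3, a log2 fold change of 1 or more left 1219 and 677, and 1208 and 566, and glmTreat 479 and 252, and 471 and 216, stricter by construction. Limma without a filter called 3202 lower at E5. For E7 against E5, DESeq2 called 6 and 6 and found 6 patterns, and limma called 1 and 1 with a pseudocount of 0.1 and 1 and 1 without a filter. The cause of these was not tested. RLE factors gave 2106 and 2156, and 2005 and 1964, library size alone 1652 and 2955, and 1628 and 2577, DESeq2 2499 and 2512, and 2448 and 2295, and unsummed entries 2000 and 1760, and 1887 and 1897. DESeq2 gave no adjusted p for 6, 6 and 1 named genes in E5 against E3, E7 against E3 and E7 against E5. Replicate numbers did not pair the libraries (r of deviations -0.48, -0.35 and -0.77 for E5 and E7, 0.01, 0.08 and 0.07 for E3 and E5, 0.01, 0.04 and 0 for E3 and E7); with the number as a block, 1603 and 1525, 0 and 0, and 1466 and 1431 genes were called for E5 against E3, E7 against E5 and E7 against E3. The block ended the calls of 28 of 139 named genes in E5 against E3 and of 29 of 138 in E7 against E3, limma on log2(FPKM + 1) of 7 of 134 and 9 of 132, library size alone of 4 of 139 and 1 of 138, DESeq2 of 2 of 133 and 1 of 132, and RLE factors of none. The third libraries were dropped because they stood apart, so the 1350 higher and 1371 lower genes of E7 against E5 and the 2051 patterns this gave are circular; E5 against E3 gave 3072 and 2910, and E7 against E3 2589 and 2508. In that setting ATP1B1 at E5 fell by 0.36 (adjusted p = 0.0229), reversed from the main fit, where it was not called. The collagens in E7 against E5 had a median of -0.59 (camera, lower, adjusted p = 6.37e-06). Their median was already -0.26 in the main fit, so only the direction of camera was reversed, from higher and not called (adjusted p = 0.983). The cause of either was not tested. The E7 libraries, with 9874339 to 13740392 counts, limit what could be seen of low genes.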

Other observations

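The immediate early genes EGR1 and FOS were higher and the heat shock genes HSP90AA1 and HSPH1 lower in both corneal groups than at E3. This part holds no test chosen after the result was seen. EGR1 rose from 3.64 ± 1.11 to 31.6 ± 14.7 FPKM at E5 (mean ± SD, n = 3; log2 fold change 3.31 ± 0.37, edgeR adjusted p = 0.00053) and to 27.2 ± 0.578 FPKM at E7 (3.04 ± 0.37, adjusted p = 0.000754), and FOS from 24.3 ± 4.86 to 67.5 ± 5.05 FPKM (1.65 ± 0.34, adjusted p = 0.00715) and 121 ± 58.8 FPKM (2.43 ± 0.35, adjusted p = 0.00162). HSP90AA1, a chaperone, fell from 1079 ± 124 to 479 ± 53.2 FPKM (adjusted p = 0.00164) and 556 ± 120 FPKM (-0.82 ± 0.14, adjusted p = 0.00388), and HSPH1 from 63.9 ± 0.480 to 19.7 ± 5.65 FPKM (-1.53 ± 0.21, adjusted p = 0.00132) and 21.8 ± 5.70 FPKM (-1.43 ± 0.21, adjusted p = 0.00189). Of 14 genes of this list, 6 rose and 4 fell in each comparison, and 7 and 4 at E5 and 9 and 5 at E7 adjusted over the list alone (camera adjusted p = 0.424 and 0.284).

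Of 61 cytoplasmic ribosomal protein genes, RPS27 and RPLP0 rose and RPL3 fell at E5, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.902), and 5 rose and 1 fell at E7, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.352). RPS27 rose from 800.1 ± 51.4 to 952 ± 64.5 FPKM at E5 (0.43 ± 0.09, adjusted p = 0.00829) and to 1034 ± 54.2 FPKM at E7 (0.50 ± 0.09, adjusted p = 0.00443), changes of a size that depends on the scaling. At E5 the call of RPLP0 was lost without E3 library 1 or 2, at up to 0.0643, and that of RPL3 without any library but E7 library 3, at up to 0.142. HOX genes summed to 0 to 0.6 CPM in each of the 9 libraries and were not tested, and no entry matched a mitochondrial gene of that list.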
